A study of Arabidopsis thaliana with 12 samples.

How the data were processed

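Transcript levels were measured in the aerial parts of 2-week-old Arabidopsis thaliana plants with Affymetrix ATH1 arrays hybridised with biotin-labelled material from total RNA. The 12 arrays fell into 6 groups of 2: the Columbia wild type (WT), the mutants cpr5 and npr1, the double mutant cpr5npr1, cpr5 carrying scv1 (cpr5scv1), and cpr5npr1 carrying svi1 (cpr5npr1svi1). The plants grew at 23 C and 70% humidity under a 16 h photoperiod, per the labels. Nothing in the labels says whether the 2 arrays of a group came from separately grown plants, so p-values measure only the spread between these arrays, which may be technical.

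The deposited values are MAS5 signal on a linear scale, per the submitters' processing notes; the MAS5 version, the detection calls and the scaling settings are not given in the sources used here. The deposited signal of each of the 22810 probe sets was above 0, and after the lowest and highest 2% were left out its mean was 100.01 in every array, so each array had been scaled to one target. The median signal without control sets ranged from 36.8 to 43.5 between arrays. No further normalization was applied. The 64 control probe sets and, of the other 22746, the dimmest 30% by mean log2 signal over all 12 arrays were left out, which left 15923 probe sets for testing. No pseudocount was added.

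Genes were named through the platform annotation and a gene table of the assembly TAIR10.1. Of the 22746 probe sets, 13513 had 1 gene, 503 had several and 8730 had none listed; 13436 were linked to a locus, and 1551 of these carried a symbol other than the locus code. Probe sets with several genes or none were tested but not named, so many well-known genes are not analysed here by name. CPR5, NPR1, PR1, PR2 and PR5, which were to be reported in every group, had no named probe set, so the mutated genes could not be used to check the labels. The annotation names no matching build, so genes are placed by locus code only.

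Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit, eBayes with an intensity trend) in one model of 6 group means over 12 arrays, with 6 residual degrees of freedom and 4.65 prior degrees of freedom. A probe set was called at a Benjamini-Hochberg adjusted p below 0.05 within each of 10 contrasts, 1 of them the interaction of cpr5 and npr1. Fold changes are on the log2 scale of the signal. An adjusted p of a single gene comes from this model unless another setting or an omitted array is named with it.

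Named genes were chosen by a rule fixed before the data were examined: per comparison, up to 8 rises and 8 falls with the largest change among called, named probe sets whose arrays did not overlap between the groups and whose brighter group mean reached the median of all probe sets, a signal of 40.8; up to 4 called members of each fixed gene list, or, where none was called, up to 2 members given as values; and CPR5, NPR1, PR1, PR2, PR5 and PDF1.2 in every group. For the interaction the condition on overlap was not applied, since it sets 4 groups against each other. The following were chosen after their values were seen: members of the added lists, AT2G23680 in npr1, unnamed probe sets, and genes compared between the scv1 and svi1 contrasts.

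Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a contrast, with camera at an estimated correlation and fry beside it. Of several probe sets of a gene, the brightest was used. Counts of called members were not tested against the share called over all probe sets. Of the 19 lists fixed before the data were examined, with 318 genes, only 43 genes had a named probe set and 39 were tested, and 8 lists had the 3 members a test needed. A further 19 lists were drawn up from gene symbols and chromosomes after the annotation was read and before any comparison was computed, of which 17 were tested; some share genes with the fixed lists. Median shifts of probe sets that respond to cpr5 were measured in arrays other than those that chose them, and were set beside 10000 random lists of the same size.

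Background was taken as the 95th percentile of 27 bacterial control sets over all arrays, a signal of 7.76, a choice made after the data were examined. Where 1 or both arrays of the dimmer group lay below it, the fold is given as a lower bound, with each such array raised to that level. For runs of neighbouring genes, the median log2 difference was taken over windows of 21 genes in the gene order of TAIR10.1, and a run needed at least 20 genes in a row with a running median beyond 0.5 in either direction; runs were found in replicate 1 and measured in replicate 2. This search was chosen after the data were examined.

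The replicate numbers came from the sample titles. Between all 15 pairs of groups, the differences between replicates 1 and 2 correlated at 0.175 to 0.363, so the numbers were taken to pair the arrays. For 11 of 12 arrays, the closest array of another group had the same replicate number. The main model leaves this pairing out, so its spread includes differences between replicates 1 and 2. The fit with the replicate number as a block is given, beside the results or in the closing part, where it loses a call or moves a count by over 1.5 times. Calls gained with the block are counted there and only some are named. The 2 arrays of a group correlated at 0.930 to 0.967. In 20 simulated data sets of 15923 probe sets for cpr5 versus WT, 100 probe sets were changed per fold size. The test recovered 31.6% of 2-fold and 81.7% of 4-fold changes, and 4.35% of its calls were false. A separate simulated set had 14 false calls among 133. Far fewer probe sets were changed than the 1387 called in the data, and the cutoff for a call depends on that number. The simulated values had no replicate effect and no correlation between probe sets. These rates therefore do not give those of the real comparison. A simulated run of 121 shifted genes was found whole, and no run was found without one. The simulated shift was about as large as in the runs seen, and the values had no replicate effect and no correlation between neighbours. The set without a shift was drawn once, so the simulation does not give the rate of false runs.

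Alternatives covered quantile normalization, scaling to one median, a pseudocount of 32, no filter or a filter of 50%, no intensity trend, fits of only the groups compared, the replicate block, a 2-fold minimum and leaving out each array. An array left out leaves its group with 1 array, which is then assumed to vary like the other groups. These fits had no replicate block, so leaving out an array also mixes any difference between replicate numbers into the comparison. The median log2 signal of all probe sets was 0.195 higher in cpr5 than in WT, 0.193 higher in cpr5npr1, 0.192 in cpr5scv1 and 0.193 in cpr5npr1svi1, and 0.143 higher in cpr5npr1 than in npr1, so scaling to one median lowers every such change by that much. With 2 arrays per group, the number of arrays limits the precision.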

Results

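The data set holds the signal of 22746 probe sets and 64 control sets from each of 12 arrays, 2 for each of 6 genotypes of Arabidopsis. The cpr5 mutant forms lesions and keeps defence genes active without a pathogen, and NPR1 is a co-activator of salicylic acid responses. The labels give cpr5npr1 as resistant to a downy mildew, describe scv1 as a suppressor with which cpr5 plants are again susceptible to it, and give svi1 only as part of a triple mutant. The comparisons ask what cpr5 changes, how much of that depends on NPR1, and what scv1 and svi1 change in cpr5 plants. From 76.9% to 79.5% of probe sets per array lay above background.

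**Figure D1:**
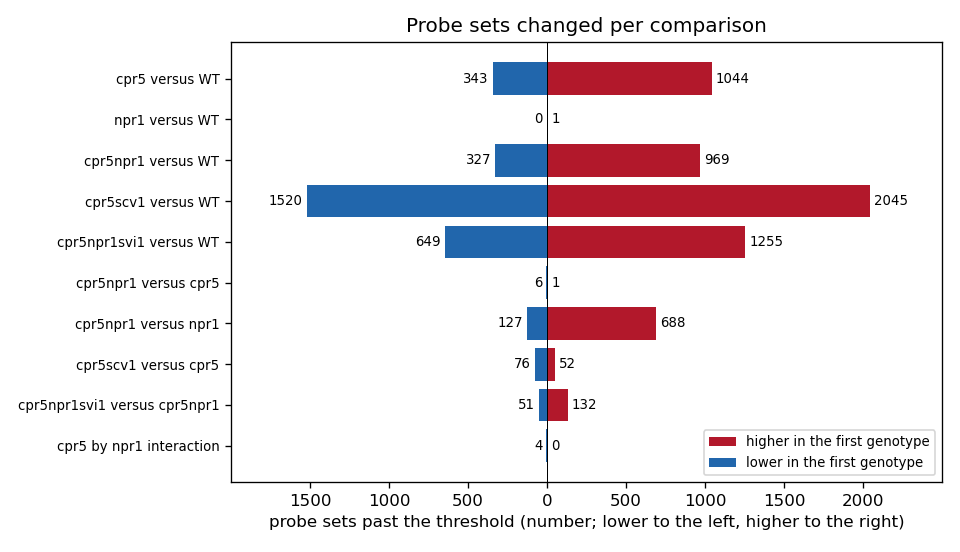
Number of probe sets past the threshold in each comparison, with those higher in the first genotype drawn to the right and those lower to the left. The npr1 mutation alone gave 1 call, and cpr5scv1 versus WT gave 2045 higher and 1520 lower.

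Several of the largest rises in cpr5 started near background in WT. OSM34, an osmotin-like protein, had a signal of 558 ± 180 (SD, n = 2) in cpr5 and 2.59 ± 1.87 in WT, at least 70.0-fold higher (adjusted p = 7.32e-05). The chitinase gene CHI (AT2G43570) rose 65.4-fold, from 16.4 ± 9.7 to 997 ± 324 (adjusted p = 9.79e-05). AT1G30700, a berberine bridge enzyme-like gene, was at least 17.1-fold higher (adjusted p = 0.000465), and AT2G44240 at least 24.6-fold (adjusted p = 0.00223). AT3G47480, below background in 1 of 2 WT arrays, was at least 19.6-fold higher, at 165 ± 55.9 (adjusted p = 0.000944). Falls were smaller: AT5G33370 fell from 199 ± 21.6 to 40.5 ± 2.15, a log2 change of -2.29 (SE 0.371, adjusted p = 0.00356), and AT3G46490 by 2.26 on the log2 scale (SE 0.317, adjusted p = 0.00175). The thionin gene THI2.2 had a log2 change of -2.64 (adjusted p = 0.00911), a call lost without cpr5 replicate 2 (adjusted p = 0.0849) and when only cpr5 and WT were fitted (adjusted p = 0.0976).

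In all, 1387 probe sets changed in cpr5, 1044 higher and 343 lower. The share that was higher, 75.3%, was 69.2% after quantile normalization and 45.8% after scaling to one median. The count was 2773 with the replicate block, 584 without cpr5 replicate 1 and 535 without cpr5 replicate 2.

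Among the fixed salicylic acid and systemic resistance genes, 2 of the 3 measured rose in cpr5, and 3 when adjusted over the list alone. The glutaredoxin gene GRX480 went from 18.1 ± 7.02 to 135 ± 4.94 (adjusted p = 0.0211), and AT5G52810 from 51.6 ± 28.5 to 169 ± 17.2 (adjusted p = 0.00708). SAG101, a partner of the immune regulator EDS1, had 43.0 ± 4.46 against 19.6 ± 3.96 and passed only over the list alone (adjusted p = 0.0606 over all genes). The list had an adjusted p of 0.00744 in camera, and an adjusted p = 0.18 with an estimated correlation. The GRX480 call was lost without WT replicate 2 (adjusted p = 0.0776), cpr5 replicate 1 (0.106) or cpr5 replicate 2 (0.109). That of AT5G52810 was lost without cpr5 replicate 2 (0.0613) and when only cpr5 and WT were fitted (0.0723).

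Cold and abscisic acid genes rose in 2 of 4 cases, both over all genes and over the list alone, but the list did not pass (adjusted p = 0.186). COR15A, which protects chloroplasts in the cold, had 177 ± 71.6 in cpr5 and 35.8 ± 6.91 in WT (log2 change 2.26, SE 0.27, adjusted p = 0.000616). The other call, COR15B (adjusted p = 0.0319), was lost without either WT array (0.0954 and 0.0764) or either cpr5 array (0.23 and 0.0564). It was also lost after quantile normalization (0.0824), after scaling to one median (0.0707), with no filter (0.0532) and when only cpr5 and WT were fitted (0.152). In the endoplasmic reticulum folding list, 2 of 3 genes rose, and 3 over the list alone, with an adjusted p of 0.0106, and an adjusted p = 0.27 with an estimated correlation. The co-chaperone gene ATERDJ3B went from 229 ± 32.2 to 482 ± 97.8 (adjusted p = 0.011), and the calreticulin gene CRT1b from 491 ± 26.9 to 735 ± 111 (adjusted p = 0.0471). The CRT1b call was lost when any of the 12 arrays was left out (adjusted p 0.0548 to 0.287). It was also lost after scaling to one median (0.181), with no filter (0.0563), with no intensity trend (0.0878) and when only cpr5 and WT were fitted (0.194). The ATERDJ3B call was lost without WT replicate 1 (0.0622) or cpr5 replicate 2 (0.101) and when only cpr5 and WT were fitted (0.0695), and the list call without cpr5 replicate 2 (0.0501).

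The remaining fixed lists with at least 3 measured genes did not pass in cpr5. Senescence genes rose in 1 of 3 cases, over all genes and over the list alone: the transcription factor gene WRKY53 went from 29.0 ± 2.34 to 94.0 ± 16.6 (adjusted p = 0.0129), a call lost without WT replicate 1 (0.0557) or cpr5 replicate 2 (0.101). Auxin and cell wall loosening genes rose in 2 of 4 cases, with 2 higher and 1 lower over the list alone, led by GH3.3, an auxin-conjugating enzyme gene, at 140 ± 39.3 against 55.1 ± 2.61 (adjusted p = 0.0143; lost without WT replicate 1, 0.0576, without cpr5 replicate 2, 0.125, and when only cpr5 and WT were fitted, 0.0566). The other call, WES1, was lost without WT replicate 1 (0.052), cpr5 replicate 1 (0.0794) or cpr5 replicate 2 (0.076), and when only cpr5 and WT were fitted (0.0525). None of 4 photosynthesis, 3 cell cycle and 3 anthocyanin genes was called, with adjusted p of 0.187, 0.186 and 0.322 for the lists; with the replicate block, the anthocyanin gene DFR was called (adjusted p = 0.0167), at 438 ± 55.2 against 219 ± 9.22.

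The fixed list of aliphatic glucosinolate synthesis had 2 measured genes, too few to test as a list, and both fell in cpr5. BCAT4 went from 1446 ± 112 to 964 ± 9.18 (log2 change -0.58, SE 0.141, adjusted p = 0.029). The call was lost without either array of WT, cpr5 or cpr5scv1 (0.0507 to 0.147), after quantile normalization (0.0929), with no intensity trend (0.0631) and when only cpr5 and WT were fitted (0.144). AT2G31790 went from 361 ± 35.3 to 214 ± 4.32 (-0.76, SE 0.176, adjusted p = 0.0239), lost without WT replicate 2 (0.0868), cpr5 replicate 1 (0.112) or 2 (0.128), and when only cpr5 and WT were fitted (0.105). In cpr5npr1 both were also lower than in WT. BCAT4 fell by 0.64 (adjusted p = 0.0192; lost without WT replicate 2, 0.0756, without cpr5npr1 replicate 1, 0.16, and when only these groups were fitted, 0.204). AT2G31790 fell by 0.68 (adjusted p = 0.0385), lost when any 1 array other than those of cpr5scv1 was left out (0.0509 to 0.195), with no intensity trend (0.0673) and when only these groups were fitted (0.178). In cpr5scv1, AT2G31790 fell by 1.48 (adjusted p = 0.000257), a call held in all 12 fits, and BCAT4 by 0.65 (adjusted p = 0.00828; lost without cpr5scv1 replicate 1, 0.0638, and when only these groups were fitted, 0.0509). In cpr5npr1svi1, AT2G31790 alone was called, and fell by 0.93 (adjusted p = 0.00698; lost without cpr5npr1svi1 replicate 2, 0.0678, and when only these groups were fitted, 0.0611).

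Of the lists drawn up from gene symbols and chromosomes, 5 passed in cpr5 at the preset correlation and 0 with an estimated one. The 69 chloroplast-encoded genes had a median log2 change of -0.40 (adjusted p = 6.91e-08 in camera, and an adjusted p = 0.18 with an estimated correlation). Over all 15923 probe sets tested 343 were called lower, and of these 69 genes 2 were. The count was 1 without WT replicate 1 or either array of cpr5, npr1 or cpr5scv1. One of the called genes, the NAD(P)H dehydrogenase subunit gene ndhJ, fell from 1460.0 ± 80.3 to 786 ± 65.9 (adjusted p = 0.00293). The 32 nuclear photosynthesis and chlorophyll genes had a median of -0.34, with 3 lower, 1 without either WT array and 0 without either cpr5 array (adjusted p = 2.21e-05, and an adjusted p = 0.18 with an estimated correlation). Autophagy genes rose in 3 of 10 cases, and in 0 without cpr5 replicate 2 (adjusted p = 0.00153, and an adjusted p = 0.18 with an estimated correlation), among them APG8A, from 117 ± 16 to 245 ± 30.5, and ATG8H, from 47.3 ± 6.33 to 108 ± 24.6, whose calls were lost without cpr5 replicate 2 (adjusted p = 0.0829 and 0.0685).

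Glutamate receptor-like channel genes rose in 3 of 7 cases in cpr5 (adjusted p = 0.0142, and an adjusted p = 0.18 with an estimated correlation; lost without WT replicate 2, 0.067, or cpr5 replicate 1, 0.0539). GLR2.7 went from 14.0 ± 3.97 to 120 ± 26.3, a log2 change of 3.11 (SE 0.252, adjusted p = 6.03e-05). Among endoplasmic reticulum stress genes 2 of 15 rose, ATERDJ3B and CRT1b (adjusted p = 0.00201, and an adjusted p = 0.18 with an estimated correlation). The count was 0 without WT replicate 1 or cpr5 replicate 2, and 1 when any other array but WT replicate 2 was left out. The cytochrome P450 gene CYP71B23, below background in 1 of 2 WT arrays, was at least 17.5-fold higher (adjusted p = 4.34e-05), at 161 ± 26.7, and the sugar transporter gene SWEET8 rose by a log2 change of 1.63 (adjusted p = 0.00293), from 13.7 ± 1.83 to 42.3 ± 3.94.

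In plants that carried npr1, the comparison of cpr5npr1 with npr1 asks for the cpr5 effect without functional NPR1. OSM34 had 360 ± 52.3 in cpr5npr1 and 1.31 ± 1.22 in npr1, at least 46.2-fold higher (adjusted p = 9.08e-05), and CHI rose 44.9-fold, from 16.6 ± 7.97 to 780 ± 481 (adjusted p = 0.000253). AT1G26390, another berberine bridge enzyme-like gene, lay below background in 1 of 2 npr1 arrays and was at least 56.2-fold higher in cpr5npr1, at 466 ± 173 (adjusted p = 0.000263). COR15A rose from 23.8 ± 0.89 to 151 ± 29.5 (log2 change 2.65, SE 0.27, adjusted p = 0.000308). The pectin methylesterase gene PME61 fell from 144 ± 36.6 to 35.8 ± 0.381, a log2 change of -1.99 (SE 0.224, adjusted p = 0.00054), and AT3G46490 fell by 2.04 on the log2 scale (SE 0.317, adjusted p = 0.00364).

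Salicylic acid genes rose in 2 of 3 cases in cpr5npr1 against npr1, and 3 over the list alone (adjusted p = 0.00497, and an adjusted p = 0.289 with an estimated correlation). SAG101 had 58.8 ± 30.1 against 15.7 ± 0.0391 (adjusted p = 0.0103), a call lost without npr1 replicate 1 (0.0656), npr1 replicate 2 (0.0592) or cpr5npr1 replicate 1 (0.0926). The call of AT5G52810 (adjusted p = 0.0447) was lost when any 1 array other than those of WT was left out (0.0534 to 0.326), and with quantile normalization, median scaling, no filter or no intensity trend (0.0552 to 0.07). Without npr1 replicate 1 or cpr5npr1 replicate 1, 0 were called. GRX480 had 64.8 ± 25.3 against 21.4 ± 22.4 and was not called (adjusted p = 0.116). Autophagy genes rose in 4 of 10 cases, 1 without npr1 replicate 1 and 2 without cpr5npr1 replicate 1 (adjusted p = 0.000465, and an adjusted p = 0.289 with an estimated correlation), with ATG8H at 116 ± 6.86 against 39.7 ± 4.69 (adjusted p = 0.00162). GLR2.7 rose by a log2 change of 2.21 (adjusted p = 0.000555) and SWEET8 by 1.87 (adjusted p = 0.00162), and CYP71B23 was at least 14.2-fold higher (adjusted p = 9.08e-05), with 1 of 2 npr1 arrays below background.

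Nuclear photosynthesis genes were lower as a list in cpr5npr1 than in npr1, with none of 32 called (adjusted p = 0.00497, and an adjusted p = 0.313 with an estimated correlation; 0.0595 after quantile normalization, 0.0976 without npr1 replicate 1 and 0.148 without cpr5npr1 replicate 1). Cold and abscisic acid genes rose in 1 of 4 cases, and 2 over the list alone (adjusted p = 0.0376, and an adjusted p = 0.313 with an estimated correlation; 0.0586 with the replicate block, 0.052 with a pseudocount of 32, 0.122 without npr1 replicate 1 and 0.148 without cpr5npr1 replicate 1). Senescence genes (1 of 3 called) and endoplasmic reticulum folding genes (1 of 3 called) did not pass as lists, both with an adjusted p of 0.0815. The called senescence gene, WRKY53, was lost without npr1 replicate 1 or either array of cpr5, cpr5npr1 or cpr5scv1 (0.0673 to 0.309). It was also lost with quantile normalization, median scaling, a pseudocount of 32, no filter, no intensity trend, or only the groups compared (0.0625 to 0.0938). The called folding gene, ATERDJ3B, was lost without either array of npr1, cpr5npr1, cpr5scv1 or cpr5npr1svi1 (0.0533 to 0.286), after scaling to one median (0.0882), with no intensity trend (0.0698) and when only cpr5npr1 and npr1 were fitted (0.077).

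This comparison gave 815 calls, 688 higher and 127 lower, of which 84.4% were higher, against 80.2% after quantile normalization and 67.6% after scaling to one median. The count was 1649 with the replicate block, 403 without npr1 replicate 1, 488 without npr1 replicate 2 and 289 without cpr5npr1 replicate 1. It shares no array with cpr5 versus WT, and across the probe sets tested, which are not independent replicates, the log2 changes of both correlated at r = 0.79 (0.687 in replicate 1 and 0.646 in replicate 2). With no filter, r was 0.470. Of the calls, 578 were higher in both, where independent lists would share 45.1, 80 were lower in both, where 2.74 would be shared, and 0 went opposite ways. Both comparisons use the same estimate of spread per probe set, so probe sets with a low spread are more readily called in both. The numbers for independent lists are therefore too low a baseline.

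**Figure D2:**
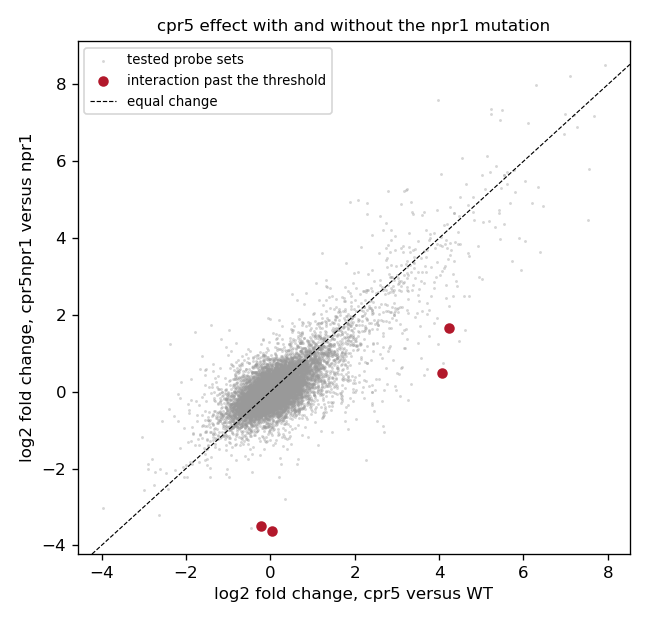
Log2 fold change of each tested probe set in cpr5 versus WT (horizontal) and in cpr5npr1 versus npr1 (vertical), with the line of equal change dashed and probe sets with an interaction past the threshold in red. The cloud follows the line, r = 0.79, and the 4 red points lie below it.

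Without the replicate block, 1 probe set was called in npr1 versus WT and 7 in cpr5npr1 versus cpr5, against 4 and 15 with it. With 2 arrays per group, few calls do not show that npr1 changed few genes. AT2G23680 was below background in both WT arrays and had 21 ± 1.77 in npr1, at least 2.70-fold higher (adjusted p = 0.00208). With a pseudocount of 32 or a filter of 50% the npr1 comparison gave 0 calls. In cpr5npr1, the neighbours AT1G26640 and AT1G26650 were near background, with signals of 7.74 ± 3.81 and 6.99 ± 0.342, against 129 ± 10.3 and 122 ± 21 in cpr5, 90.4 ± 21.3 and 83.7 ± 39.8 in npr1, and 125 ± 18.4 and 142 ± 14.3 in WT. Against cpr5, AT1G26640, with 1 of 2 cpr5npr1 arrays below background, was at least 14.3-fold lower and AT1G26650 at least 15.6-fold (adjusted p = 0.000453 for both). AT4G21870 rose from 222 ± 41.5 to 861 ± 168 (adjusted p = 0.0186), a call lost without cpr5 replicate 2 (0.301), cpr5npr1 replicate 2 (0.213), cpr5scv1 replicate 1 (0.0582) or cpr5scv1 replicate 2 (0.0583), without the intensity trend (0.0751), and when only cpr5npr1 and cpr5 were fitted (0.0613).

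The other 4 calls in cpr5npr1 against cpr5 were unnamed probe sets, all lower in cpr5npr1. The brightest had a mean signal of 2012 in cpr5, 193 in cpr5npr1, 33.0 in WT and 21.2 in npr1 (log2 change -3.43, adjusted p = 0.00125). The next had 505 in cpr5, 55.4 in cpr5npr1, 30.3 in WT and 40.0 in npr1 (log2 change -3.18, adjusted p = 0.00351; 0.0735 without cpr5 replicate 2). A set with 101 in cpr5 and 20.8 in cpr5npr1 (log2 change -2.23, adjusted p = 0.0437) was lost without any array but WT replicates 1 and 2 and cpr5 replicate 1 (0.0782 to 0.589). The dimmest, with 56.7 and 8.94 (log2 change -2.68, adjusted p = 0.00531), was lost without cpr5 replicate 1 (0.0577), cpr5 replicate 2 (0.0852) or cpr5npr1 replicate 2 (0.0749).

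At an unadjusted p below 0.05, limma counted 899 probe sets in npr1 versus WT (5.65% of those tested) and 621 in cpr5npr1 versus cpr5 (3.9%). With no change at all, a fraction of about 0.05 would pass, so the first count lies close to this level and the second below it. With the replicate block they were 1578 and 1141, above this level. The counts that follow are of calls at an adjusted p below 0.05. For npr1 versus WT the count was 4 with the replicate block, 12 without WT replicate 1, 304 without WT replicate 2 and 2 without npr1 replicate 2. For cpr5npr1 versus cpr5 it was 15 with the block, 11 without WT replicate 1, WT replicate 2 or cpr5 replicate 1, and 4 without cpr5 replicate 2.

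Of 25 lists tested in cpr5npr1 versus cpr5, 1 passed as higher and 1 as lower at the preset correlation, and 0 with an estimated one. The list that passed as higher is not described here. Auxin and cell wall loosening genes were lower in cpr5npr1 than in cpr5 as a list of 4 (median log2 change -0.95, adjusted p = 0.00077, and an adjusted p = 0.604 with an estimated correlation). None was called singly and 1 was over the list alone; GH3.3 had 67.3 ± 24.4 against 140 ± 39.3. The list call was lost without cpr5 replicate 2 (0.0544) or cpr5npr1 replicate 1 (0.12). The 3 measured of the 30 salicylic acid genes did not pass as a list (0 of 3 called, adjusted p = 0.827). PR1, PR2 and PR5 were not among them, so this does not show whether the other salicylic acid genes depended on NPR1 in cpr5 plants. In npr1 against WT the chloroplast-encoded genes were lower as a list, with none of 69 called (median -0.25, adjusted p = 8.95e-09, and an adjusted p = 0.624 with an estimated correlation; lost without npr1 replicate 2, 0.151). The list expansins and xyloglucan endotransglucosylases in npr1 versus WT was higher, with none of 18 genes called (adjusted p = 0.0498, an adjusted p = 0.745 with an estimated correlation, and 0.0609 with the replicate block; 0.577 without WT replicate 1, 0.0792 without npr1 replicate 1 and 0.151 without npr1 replicate 2).

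The interaction of cpr5 and npr1 tests whether the cpr5 effect differed with npr1. At an unadjusted p below 0.05 it had 507 probe sets (3.18%), below the fraction of 0.05 that would pass with no change, and 1036 with the replicate block. After adjustment it gave 4 calls. They were the unnamed probe set with 505 in cpr5 and 55.4 in cpr5npr1 (-3.60 on the log2 scale, SE 0.446, adjusted p = 0.0393), AT1G26640 (adjusted p = 0.0393), AT1G26650 (adjusted p = 0.043) and AT2G23680 (adjusted p = 0.0393). The sizes of the last 3 are bounds, since 1 cpr5npr1 array, both cpr5npr1 arrays and both WT arrays lay below background. With these raised to it, the differences were -3.36, -3.12 and -1.31. With a pseudocount of 32, these calls were lost (adjusted p = 0.0742, 0.753 and 1), and that of AT1G26650 also after scaling to one median (0.0511). The calls of the unnamed probe set and AT2G23680 held only without WT replicate 1 or 2, that of AT1G26650 only without WT replicate 2 or npr1 replicate 1, and that of AT1G26640 only without WT replicate 2 or either cpr5npr1 array; the other fits gave adjusted p of 0.0551 to 0.301. The count was 163 without WT replicate 2, 1 without npr1 replicate 1 or cpr5npr1 replicate 2, and 0 without either array of cpr5, cpr5scv1 or cpr5npr1svi1 or npr1 replicate 2. It was also 0 with no filter, with no intensity trend and with only the 4 groups fitted.

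In the interaction, auxin and cell wall loosening genes were lower as a list of 4, with none called and 2 over the list alone (adjusted p = 0.0365, and an adjusted p = 0.72 with an estimated correlation; 0.0734 with the replicate block and 0.0778 with a pseudocount of 32). Without WT replicate 1 the adjusted p was 0.221, without cpr5 replicate 2 0.159, without npr1 replicate 2 0.127 and without cpr5npr1 replicate 1 0.251. The 69 chloroplast-encoded genes were higher as a list, with none called (median 0.44, adjusted p = 4.41e-11, and an adjusted p = 0.39 with an estimated correlation). The 3 measured of the 30 salicylic acid genes did not pass as a list (0 of 3 called, adjusted p = 0.851), which leaves the others of the list untested.

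Against WT, the double mutant cpr5npr1 had high levels of OSM34 and of AT1G26390, a berberine bridge enzyme-like gene. OSM34 was at least 46.2-fold higher (adjusted p = 0.000123), AT1G26390 at least 57.9-fold (adjusted p = 0.000415) and AT5G52760 at least 30.8-fold (adjusted p = 6.62e-05). AT3G46490 fell by 2.67 on the log2 scale (SE 0.317, adjusted p = 0.000635) and AT4G01390 by 2.45 (SE 0.383, adjusted p = 0.00291). Salicylic acid genes rose in 2 of 3 cases, and 3 over the list alone (adjusted p = 0.0158, and an adjusted p = 0.286 with an estimated correlation; lost without cpr5npr1 replicate 1, 0.0515). Both called members were lost without cpr5npr1 replicate 1 (SAG101 0.173, AT5G52810 0.118), and when only these groups were fitted (0.16 and 0.117). SAG101 was also lost without WT replicate 1 (0.0986). Autophagy genes rose in 3 of 10 cases, 1 without cpr5npr1 replicate 1 (adjusted p = 0.000539, and an adjusted p = 0.286 with an estimated correlation). Nuclear photosynthesis and chlorophyll genes passed as lower in camera at the preset correlation, with 2 of 32 called (adjusted p = 7.21e-05). The chloroplast-encoded list was drawn up by chromosome and is not limited to photosynthesis. It also passed as lower in camera (adjusted p = 8.62e-05, and 0.594 after quantile normalization), with none of 69 called. Each list had an adjusted p = 0.286 in camera with an estimated correlation. The nuclear count was 0 or 1 when any 1 array other than cpr5npr1 replicate 2 was left out. There were 1296 calls, 969 higher and 327 lower, with 74.8% higher, 69.3% after quantile normalization and 46.3% after scaling to one median. The count was 2574 with the replicate block and 453 without cpr5npr1 replicate 1.

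In cpr5scv1, OSM34 and CHI were far above WT. OSM34 was at least 44.4-fold higher (adjusted p = 4.66e-05), AT1G26390 at least 79.4-fold (adjusted p = 1e-04) and the phosphatase gene SAL2 at least 26.5-fold, at 211 ± 66.5 against 2.31 ± 0.577 (adjusted p = 9.99e-06). CHI reached 1473 ± 591, 95.2-fold above WT (adjusted p = 2.67e-05). Among falls, AT1G60590 went from 214 ± 35.3 to 26.8 ± 3.67 (adjusted p = 1.61e-05) and AT2G29300 from 128 ± 13.8 to 12.9 ± 3.04, a log2 change of -3.33 (SE 0.345, adjusted p = 0.000107).

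All 3 salicylic acid genes rose in cpr5scv1, also over the list alone (adjusted p = 0.0117, and an adjusted p = 0.184 with an estimated correlation): GRX480 to 180 ± 28.9 (adjusted p = 0.00511), SAG101 to 72.6 ± 8.47 (adjusted p = 0.00259) and AT5G52810 to 178 ± 0.82 (adjusted p = 0.0025). In the endoplasmic reticulum folding list 2 of 3 rose, also over the list alone (adjusted p = 0.0314, and an adjusted p = 0.275 with an estimated correlation), with BZIP60, a transcription factor of the unfolded protein response, at 424 ± 0.331 against 152 ± 56.1 (adjusted p = 0.00246). WRKY53 rose to 182 ± 14.5 (adjusted p = 0.000443), 1 of 2 called of 3 senescence genes (1 without either cpr5scv1 array), with 3 over the list alone (adjusted p = 0.0306, and an adjusted p = 0.184 with an estimated correlation; lost without WT replicate 2, 0.0555, or cpr5scv1 replicate 2, 0.0554). The other call, WRKY6 (adjusted p = 0.0177), was lost without WT replicate 1 (0.114) or either cpr5scv1 array (0.0705 and 0.0916). Of fixed lists too small to test, STZ of the oxidative stress list rose from 58.9 ± 23.4 to 366 ± 105 (adjusted p = 0.00746; lost without cpr5scv1 replicate 2, 0.0589). AT2G04400 of the tryptophan list went from 251 ± 6.19 to 442 ± 4.27 (adjusted p = 0.0285), lost without either array of WT (0.0942 and 0.0654) or of cpr5scv1 (0.11 and 0.113) and after scaling to one median (0.0596). Autophagy genes rose in 7 of 10 cases (adjusted p = 7.29e-05, and an adjusted p = 0.184 with an estimated correlation), and 6 of 25 exocyst and secretory genes rose, 3 without cpr5scv1 replicate 1 (adjusted p = 0.0139, and an adjusted p = 0.184 with an estimated correlation).

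Nuclear photosynthesis and chlorophyll genes passed as lower in cpr5scv1 than in WT in camera at the preset correlation (adjusted p = 0.000232, and 0.0538 after quantile normalization). Of these 32 genes 5 were called. The chloroplast-encoded list was drawn up by chromosome and is not limited to photosynthesis. It also passed as lower in camera (adjusted p = 2.71e-05, and 0.0888 after quantile normalization), with 6 of 69 genes called. Both counts were lower without some single arrays. Both lists had an adjusted p = 0.184 in camera with an estimated correlation. SBPASE, a Calvin cycle enzyme gene, fell from 3063 ± 132 to 1593 ± 43.8 (adjusted p = 0.00142). The comparison gave 3565 calls, 2045 higher and 1520 lower, with 57.4% higher, 50.4% after quantile normalization and 37.2% after scaling to one median. The 6 of 69 chloroplast-encoded genes called are no larger a share than the 1520 of all 15923 probe sets called lower. The count was 5412 with the replicate block, 1851 without cpr5scv1 replicate 1, 2106 without cpr5scv1 replicate 2, and 1971 at a change of at least 2-fold.

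Against cpr5 itself, EXO and AT3G19680 were lower with scv1. EXO, which promotes cell expansion, fell from 1064 ± 140 to 156 ± 31.5, a log2 change of -2.78 (SE 0.268, adjusted p = 0.00304), and AT3G19680 from 494 ± 57.7 to 118 ± 8.82 (-2.07, SE 0.184, adjusted p = 0.00246). Expansin and xyloglucan endotransglucosylase genes, which loosen cell walls, were lower as a list with 2 of 18 called (adjusted p = 0.00332, and an adjusted p = 0.163 with an estimated correlation; lost without cpr5 replicate 1, 0.068). The count was 0 without replicate 1 of cpr5 or cpr5scv1, and 1 without replicate 2 of either. A called member was EXGT-A3, at 416 ± 11.6 against 909.9 ± 159 (adjusted p = 0.0121), lost without cpr5 replicate 1 (0.12), cpr5scv1 replicate 1 (0.133) or cpr5scv1 replicate 2 (0.0752).

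The list of SWEET sugar transporter genes passed as lower in cpr5scv1 than in cpr5 at the preset correlation, with 2 of 11 called (adjusted p = 0.0284, and an adjusted p = 0.163 with an estimated correlation; lost without cpr5 replicate 1, 0.068, or cpr5scv1 replicate 2, 0.0869). The count was 0 without either array of cpr5 or cpr5scv1, and 1 without either of cpr5npr1 or cpr5npr1svi1. SWEET13 had 27.4 ± 1.42 against 93.4 ± 16.3 (adjusted p = 0.0121; 0.131 and 0.0675 without either cpr5 array, 0.127 and 0.0736 without either cpr5scv1 array). Senescence genes were higher as a list, with none of 3 called and 2 over the list alone (adjusted p = 0.00839, and an adjusted p = 0.163 with an estimated correlation; lost without cpr5 replicate 1, 0.0865, or cpr5scv1 replicate 2, 0.0693). Autophagy genes were also higher as a list, with none of 10 called (median 0.32, adjusted p = 0.00188, and an adjusted p = 0.163 with an estimated correlation; lost without the same arrays, at 0.0865 and 0.0693). The 3 measured of the 30 salicylic acid genes did not pass as a list (0 of 3 called, adjusted p = 0.31).

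Of the rises, AT3G23550 went from 33.4 ± 15.1 in cpr5 to 404 ± 112 in cpr5scv1 (log2 change 3.65, SE 0.45, adjusted p = 0.00693), a call lost without cpr5 replicate 1 (0.0593) or cpr5scv1 replicate 1 (0.0733). The P450 gene CYP71B22 went from 22.3 ± 5.22 to 110 ± 19.4 (2.31, SE 0.322, adjusted p = 0.0107; lost without cpr5 replicate 1, 0.103, cpr5scv1 replicate 1, 0.0733, or cpr5scv1 replicate 2, 0.0833). There were 128 calls, 52 higher and 76 lower. The count was 605 with the replicate block, 239 without either WT array, 18 and 26 without cpr5 replicates 1 and 2, and 11 and 34 without cpr5scv1 replicates 1 and 2.

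Genes that respond to cpr5 lay further from WT with scv1. Over the 815 probe sets called in cpr5npr1 versus npr1, in arrays not used here, the median change from cpr5 to cpr5scv1 in the direction of the cpr5 effect was 0.45 on the log2 scale (0.474 and 0.421 in replicates 1 and 2), and 10000 random lists gave -0.045 to 0.0069. It was 0.47 for the 688 that cpr5 raised and 0.23 for the 127 that it lowered, and 16.4% of the probe sets moved the other way. The same measure for svi1 over 1387 probe sets was -0.12, but -0.30 in replicate 1 and 0.059 in replicate 2, and 0.051 without cpr5npr1 replicate 1. For npr1 over 3565 probe sets it was -0.0098, with 0.083 in replicate 1 and -0.12 in replicate 2, and 0.098 without cpr5npr1 replicate 2.

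In the triple mutant cpr5npr1svi1, OSM34 and COR15A were high against WT. OSM34 was at least 37.7-fold higher (adjusted p = 0.000146), and AT4G39670 at least 14.8-fold (adjusted p = 3.24e-05). COR15A rose by a log2 change of 3.43 (SE 0.27, adjusted p = 6.26e-05), to 383 ± 44, and 2 of 4 cold and abscisic acid genes rose, also over the list alone (adjusted p = 0.0223, and an adjusted p = 0.335 with an estimated correlation; lost without WT replicate 2, 0.0916). AT1G13650 fell from 452 ± 69.6 to 61.2 ± 11.4, a log2 change of -2.89 (SE 0.176, adjusted p = 3.24e-05). Salicylic acid genes rose in 1 of 3 cases, and 3 over the list alone (adjusted p = 0.0493, an adjusted p = 0.335 with an estimated correlation, and 0.0729 with the replicate block; 0.0545 to 0.129 without either array of WT, cpr5, cpr5scv1 or cpr5npr1svi1). The called gene, GRX480 (adjusted p = 0.0495), was lost when any 1 array other than those of npr1 was left out (0.0604 to 0.198), and with quantile normalization, median scaling, no filter or no intensity trend (0.0608 to 0.0739). Nuclear photosynthesis genes were lower as a list, with 2 of 32 called lower and 1 higher, and 0 without WT replicate 1 or cpr5npr1svi1 replicate 2 (adjusted p = 0.0124, and an adjusted p = 0.335 with an estimated correlation; 0.153 after quantile normalization and 0.0916 without WT replicate 2). There were 1904 calls, 1255 higher and 649 lower, with 65.9% higher, 58.8% after quantile normalization and 40.1% after scaling to one median. The count was 3404 with the block, 1199 without WT replicate 1, 1089 and 745 without cpr5npr1svi1 replicates 1 and 2, and 1200.0 at a change of at least 2-fold.

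Against cpr5npr1, the triple mutant had AT1G26640 and AT1G26650 back at 135 ± 2.24 and 147 ± 29.2, rises of at least 15.0-fold (adjusted p = 0.000383) and at least 18.7-fold (adjusted p = 0.000338), with 1 of 2 and both cpr5npr1 arrays below background. AT1G63980 fell from 164 ± 17 to 26.9 ± 5.53 (log2 change -2.62, SE 0.21, adjusted p = 0.000587). AT5G50915 fell from 224 ± 72 to 47.3 ± 12 (-2.23, SE 0.271, adjusted p = 0.00957), a call lost without cpr5npr1 replicate 1 (0.0545) or cpr5npr1svi1 replicate 2 (0.0762). The count was 183, with 132 higher and 51 lower. It was 632 with the block, 318 and 320 without WT replicates 1 and 2, 91 and 90 without those of cpr5, 24 and 19 without those of cpr5npr1, 68 without either of cpr5scv1, and 34 and 8 without those of cpr5npr1svi1.

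Many of these rises lay in 2 runs of neighbouring genes on chromosome 2. The runs, AT2G36350 to AT2G41060 with 184 measured genes and AT2G43160 to AT2G45820 with 100, were found in replicate 1. In replicate 2 their 284 genes had a median log2 difference of 0.81 between cpr5npr1svi1 and cpr5npr1, or 1.75-fold, with 96.8% higher, against a median of -0.036 for the 8258 genes outside. Of the mapped rises in this comparison, 55 lay inside the runs and 16 outside. Those inside included AT2G40230 (at least 8.71-fold higher, adjusted p = 0.0158; lost without cpr5npr1 replicate 1, 0.059, cpr5npr1 replicate 2, 0.0803, or cpr5npr1svi1 replicate 2, 0.115). Against WT, 142 genes of the runs were called higher and 1 lower, and CHI, 86.1-fold higher than in WT (adjusted p = 8.36e-05), lies in the second run. On chromosome 1, the search found a run of 20 genes, AT1G60995 to AT1G61740, in cpr5npr1 against WT (median 0.73) and one of 21, AT1G33810 to AT1G34570, in cpr5scv1 against WT (median 0.56), both in replicate 1 and neither in replicate 2.

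**Figure D3:**
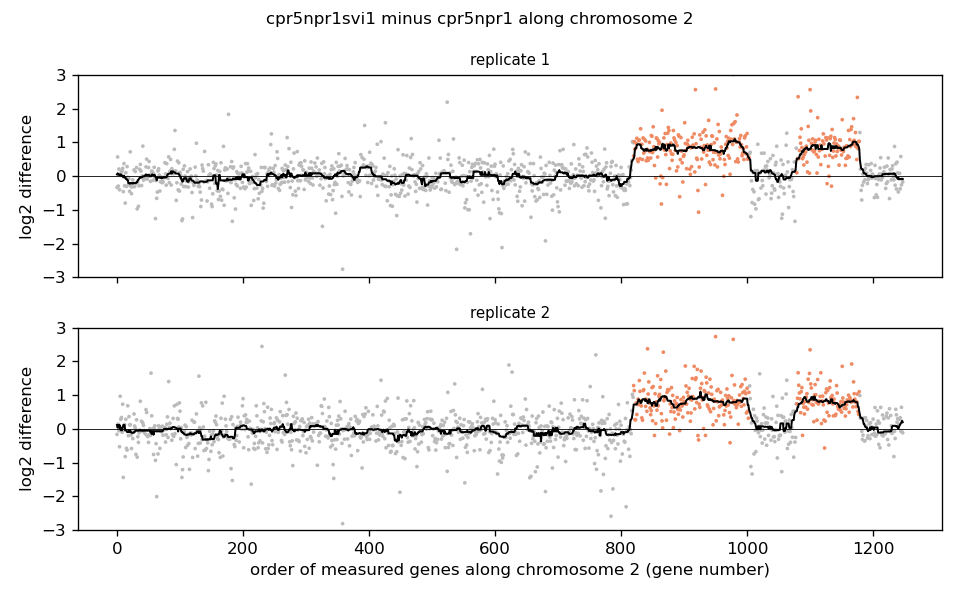
Log2 signal difference, cpr5npr1svi1 minus cpr5npr1, for each measured gene in its order along chromosome 2, with replicate 1 above and replicate 2 below; the black line is the running median, orange points are genes of the runs and points beyond the axis are not drawn. In replicate 2 the orange genes have a median of 0.81.

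Auxin and cell wall loosening genes were higher in the triple mutant than in cpr5npr1 as a list, with none of 4 called and 3 over the list alone (adjusted p = 0.00711, and an adjusted p = 0.659 with an estimated correlation; lost without cpr5npr1 replicate 1, 0.0938, or cpr5npr1svi1 replicate 2, 0.108). EXPA8, which lies in the first run, had 480 ± 121 against 69.5 ± 29, and GH3.3 had 149 ± 0.453 against 67.3 ± 24.4 and was called with the replicate block (adjusted p = 0.00818). Cold and abscisic acid genes were also higher as a list, with 1 of 4 called and 2 over the list alone (adjusted p = 0.00711, and an adjusted p = 0.659 with an estimated correlation; lost without cpr5npr1 replicate 2, 0.0916, or cpr5npr1svi1 replicate 2, 0.108). The called member was COR15A, at 383 ± 44 against 151 ± 29.5 (log2 change 1.36, SE 0.27, adjusted p = 0.0437), a call lost without either array of npr1, cpr5npr1, cpr5scv1 or cpr5npr1svi1 (0.0676 to 0.24), with no filter (0.0547), with no intensity trend (0.0785) and with only cpr5npr1svi1 and cpr5npr1 fitted (0.0602).

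PDF1.2, a defensin gene of the jasmonate and ethylene branch, was not called in any comparison. Its signal was 9.82 ± 7.55 in WT, 15.4 ± 6.65 in cpr5, 41.9 ± 56.7 in npr1, 27.0 ± 3.54 in cpr5npr1, 59.9 ± 50.7 in cpr5scv1 and 107 ± 97.7 in cpr5npr1svi1. With the replicate block it was called in cpr5npr1svi1 against WT (adjusted p = 0.0287).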

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

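The interaction of cpr5 and npr1 was planned, while all tests of an explanation in this part were chosen after the result they measure was seen. The cpr5 effect differed with npr1 in 4 probe sets. The difference on the log2 scale was -3.6 for an unnamed probe set that had 505 in cpr5 and 55.4 in cpr5npr1, -3.667 for AT1G26640, -3.27 for AT1G26650 and -2.589 for AT2G23680. The last 3 values rest on signals below background, in 1 cpr5npr1 array, both cpr5npr1 arrays and both WT arrays, and are not exact sizes. With these raised to background the differences were -3.36, -3.12 and -1.31. Each of these calls was lost in at least 9 of the fits that left out 1 array, with adjusted p of 0.0551 to 0.301, and none held without either cpr5 array. Outside the tested probe sets, 1 Arabidopsis control probe set, whose gene is not named here, had a signal of 761.2 ± 217 in cpr5scv1 and 280 ± 61.2 in cpr5, against 7.49 ± 9.4 in WT and 7.74 ± 1.63 in npr1, with 277 ± 218 in cpr5npr1 and 72.4 ± 25.7 in cpr5npr1svi1.

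The higher signal of 2 runs of chromosome 2 genes in cpr5npr1svi1 was seen in both replicates. Array scaling is argued against by a median of -0.0361 in replicate 2 for genes outside the runs, and sequence of another accession by the 94% of genes in the runs that lay above WT, since worse matching probes would lower the signal. Extra copies of the region remain a candidate explanation: among the brightest 95 genes of the runs 100% were higher in replicate 2, with a median of 1.74-fold. Whether such copies came with svi1 or arose apart from it in this line cannot be read from 1 line, and a regional change in transcription was not tested. Without these genes, cpr5npr1svi1 versus cpr5npr1 gave 128 calls. Only probe sets linked to a locus could be placed and left out, and 72 of the 132 rises were linked to one. Rises from the same region may therefore remain among the 128.

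The low signal of AT1G26640 and AT1G26650 in cpr5npr1 may be a response that cpr5 and npr1 give on their own, or come from a loss of the sequence of both genes in these plants. In cpr5npr1svi1, which also carries cpr5 and npr1, the larger log2 difference from WT was 0.117, but svi1 could reverse such a response. No line but these carries both mutations, so the response cannot be told apart from a loss. A loss would leave both genes near background, and their highest signal in the cpr5npr1 arrays was 10.4; silencing was not tested. The nearest measured genes, AT1G26620 with 29.8 ± 0.487 and AT1G26660 with 14.0 ± 4.16 in cpr5npr1, were not called against cpr5.

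Genes that respond to cpr5 lay further from WT in cpr5scv1. The labels give scv1 as a suppressor by susceptibility to a downy mildew, which is not a transcript level and was not measured here. Array scaling would move probe sets that cpr5 lowered up with the rest, but they moved down, with a signed median of 0.219 in the replicate with the lower value. RNA degradation would follow the actin 3'/5' ratio, whose log2 difference between cpr5scv1 and cpr5 was -0.639 in replicate 1 and 0.358 in replicate 2, while the shift was at least 0.421 in both. An effect of scv1 itself, on plants that may differ in lesions or stage, stays open and was not tested.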

How the results depend on the processing

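The settings listed here were planned, except the omission of the chromosome 2 genes, a test chosen after the result was seen. Of 162 gene results called as reported, 162 were called with the replicate block and 79 in all 12 fits that left out 1 array, and 0 turned direction in any setting. Calls lost were 8 with quantile normalization, 11 with median scaling, 6 with a pseudocount of 32, 16 with no filter, 26 with no intensity trend and 42 with only the groups compared. Of 53 list calls, 0 held with an estimated correlation, 9 were lost with the replicate block, 16 with quantile normalization, 5 with median scaling, 5 with no filter, 4 with a pseudocount of 32, 3 with only the groups compared and 10 with a filter of 50%. With fry, which does not compare a list with other genes, 15 were lost and 26 gained.

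With a pseudocount of 32, npr1 versus WT gave 0 calls, cpr5npr1 versus cpr5 14 and cpr5scv1 versus cpr5 240, and the scv1 shift was 0.3343. With no filter the interaction gave 0 and the correlation of the cpr5 effects was 0.4697; with a filter of 50% npr1 versus WT gave 0 and the correlation was 0.832. With no intensity trend, cpr5scv1 versus cpr5 gave 81, cpr5npr1svi1 versus cpr5npr1 84 and the interaction 0. The replicate block gave 2773 for cpr5, 4 for npr1, 2574 for cpr5npr1, 5412 for cpr5scv1 and 3404 for cpr5npr1svi1, each versus WT, 15 for cpr5npr1 versus cpr5, 1649 for cpr5npr1 versus npr1, 605 for cpr5scv1 versus cpr5 and 632 for cpr5npr1svi1 versus cpr5npr1, with a scv1 shift of 0.3112. It gained 9 gene and 3 list calls. Of its 9 list losses, 4 are given beside their results. The others were glutamate receptor-like channels in cpr5npr1 and cpr5scv1 versus WT and cpr5npr1 versus npr1 (adjusted p = 0.0634, 0.0668 and 0.0586), expansins in cpr5scv1 versus WT (0.0564) and glutathione S-transferases in cpr5npr1svi1 versus WT (0.0547). With only the groups compared, which leaves 2 residual degrees of freedom and 4 for the interaction, the counts versus WT were 516 for cpr5, 0 for npr1, 352 for cpr5npr1, 2026 for cpr5scv1 and 664 for cpr5npr1svi1, with 279 for cpr5scv1 versus cpr5, 37 for cpr5npr1svi1 versus cpr5npr1 and 0 for the interaction. At 2-fold or more, cpr5scv1 gave 1971 and cpr5npr1svi1 1200 versus WT. Apart from the fewer residual degrees of freedom, the cause was not tested.

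Leaving out 1 array gave counts of 535 to 1588 for cpr5, 1 to 304 for npr1, 453 to 1535 for cpr5npr1, 1851 to 3498 for cpr5scv1 and 745 to 2222 for cpr5npr1svi1, each versus WT. It gave 4 to 11 for cpr5npr1 versus cpr5, 289 to 1022 for cpr5npr1 versus npr1, 11 to 239 for cpr5scv1 versus cpr5, 8 to 320 for cpr5npr1svi1 versus cpr5npr1 and 0 to 163 for the interaction. The correlation ranged from 0.6931 to 0.7914, the scv1 shift from 0.4172 to 0.5527, the svi1 shift from -0.3067 to 0.05096, turned without cpr5npr1 replicate 1, and the npr1 shift from -0.1354 to 0.09841, turned without cpr5npr1 replicate 2. List calls ranged from 40 to 61. The median of the list chloroplast-encoded genes in cpr5npr1 versus npr1 ranged from -0.1899, without npr1 replicate 2, where it passed as lower, to 0.2105, without npr1 replicate 1. Without the chromosome 2 genes that could be placed, cpr5npr1svi1 gave 1761 versus WT and 128 versus cpr5npr1, with a svi1 shift of -0.1315. Any probe sets of that region without a locus stayed in. Signals near the background of 7.76 limit folds to bounds.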

Other observations

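The comparison of scv1 and svi1 effects is a test chosen after the result was seen. EXO, which promotes cell expansion, was lower with either mutation, by log2 changes of -2.78 from cpr5 to cpr5scv1 and -1.73 from cpr5npr1 to cpr5npr1svi1 (limma adjusted p = 0.00304 and 0.0212). AT5G50915 changed by -2.01 and -2.23, AT1G13650 by -1.73 and -1.42, and the xyloglucan endotransglucosylase gene EXGT-A3 by -1.12 and -0.91. AT3G23550 rose in both, by 3.65 and 3.05, and the P450 gene CYP71B6 by 1.19 and 0.85. IAGLU, an auxin glucosyltransferase gene, was called in opposite directions, at -1.23 and 0.89, but the calls did not hold. The svi1 call was lost when any 1 array other than those of WT was left out (0.0645 to 0.213), and the scv1 call without either array of cpr5 or cpr5scv1 (0.0519 to 0.141). In the svi1 comparison the calls of EXO and AT1G13650 were lost without cpr5npr1 replicate 1 (adjusted p = 0.0743 and 0.0505), cpr5npr1 replicate 2 (0.106 and 0.0601) or cpr5npr1svi1 replicate 1 (0.0732 and 0.0529). Those of AT3G23550 were lost without any array of cpr5npr1 or cpr5npr1svi1 (0.0726 to 0.108) and, in the scv1 comparison, without cpr5 replicate 1 (0.0593) or cpr5scv1 replicate 1 (0.0733). The calls of AT5G50915, EXGT-A3 and CYP71B6 were also lost without single arrays in both comparisons, with adjusted p of 0.0545 to 0.201.

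The 2 comparisons share no array, but both use the same estimate of spread per probe set. Probe sets with a low spread are more readily called in both, so the numbers for independent lists given next are too low a baseline. Of their calls, 16 were lower in both, where independent lists would share 0.243, 6 were higher in both, where 0.431 would be shared, and 1 went opposite ways, or 0 when any 1 array other than those of WT was left out. Across the probe sets tested, which are not independent replicates, the log2 changes correlated at 0.255, and at 0.146 to 0.299 when 1 array was left out. The calls lower in both numbered 33 without either WT array, 5 and 8 without cpr5 replicates 1 and 2, 0 and 2 without those of cpr5npr1, 4 and 6 without those of cpr5scv1, and 3 without either of cpr5npr1svi1. Those higher in both numbered 14 without either WT array, 3 without either npr1 array, 2 without either cpr5npr1 array, 1 without cpr5 replicate 2, cpr5scv1 replicate 2 or cpr5npr1svi1 replicate 1, and 0 without cpr5 replicate 1, cpr5scv1 replicate 1 or cpr5npr1svi1 replicate 2.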
